A study of Drosophila melanogaster with 8 samples.

How the data were processed

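Total RNA from 8 separate pools of about 240 adult female *Drosophila melanogaster* of the wild-type strain Oregon-R was compared on 8 arrays. Per the labels' protocols, flies were 4 to 10 days old, kept at 16 h light and 8 h dark and 60% relative humidity, sprayed with 2 mL of 99% ethanol from a Potter's tower (a bench device that lays down an even spray) and sampled 6 h later. For each labelling, 80 µg of total RNA was labelled directly with Cy3 or Cy5. The pools were hybridized in 4 fixed pairs, odd number against even number (pools 1 and 2, 3 and 4, 5 and 6, 7 and 8). Each pair was run on 2 arrays, once with the odd pool in Cy3 and the even pool in Cy5 (normal label) and once with the dyes exchanged (reversed label).

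The values used were the authors' deposited log2 ratios, 1 per spot for 16896 spots on each array. The log base, scanner settings, background correction and normalization within arrays are not given in the sources used here. Base 2 was inferred from the size of the values: the largest, 17.5, is a ratio of 186731 in base 2 and would be 4.02e+07 with natural logs. All statements on folds rest on that inference. No value was missing. The deposited medians of the normal-label arrays of pairs 1 to 4 were -0.00028, 4.1e-06, 0.00052 and 0.00043, and those of the reversed-label arrays 0.0011, -0.00046, -0.0023 and 0.00011. The values had thus been centred by the authors, by a method not given in the sources used here.

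Neighbouring odd and even spot numbers held the same clone: their annotation was identical for all 2909 clones listed, and their values correlated on every array. Each array's median was subtracted and the 2 spots were averaged, giving 8448 clones. GEO's platform annotation gave 1 gene symbol for 2833 clones (33.5%, 2377 genes), several for 76 and none for 5539, which are unnamed here. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GCF_000001215.4, in which all 2833 were found. That table was used for names only, and no coordinates are given because the deposited values name no build.

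The labels give the dye and pool of each channel but not which channel is the numerator. A rule fixed before the data were examined settled the orientation: normal-label and reversed-label arrays of different pairs share no RNA, and the median of their 12 correlations across clones was -0.157, below 0, so the values were likely 1 pool over the other, and reversed-label arrays were multiplied by -1 to bring all arrays to the same dye orientation. Whether the numerator was the odd or the even pool stays unknown. Dye A below means the dye of the numerator pool on normal-label arrays, dye B the other dye, and no dye or pool parity is assigned to a direction.

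Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment at 5% over 8448 clones. The dye component was the mean of the 2 arrays of a pair in dye orientation, tested against 0 over 4 pairs. The even-odd component was their difference divided by 2, tested the same way. The between-pool component was an F-test over 4 pair coefficients in a fit to all 8 arrays with a common dye intercept, which leaves 3 residual degrees of freedom before moderation, and each pair's coefficient was also tested. The residual of that fit is technical, so its calls speak of these pools only. Gene lists fixed beforehand (20, of which 19 had a clone) were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation. No clone passed the F-test, so the planned Fisher's exact tests of called list members had nothing to test.

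Replicate numbers pair the arrays because both arrays of a pair carry RNA of the same pools, and the pair was the replicate in the dye and even-odd tests. The within-pair correlation of the residuals was -0.269 in the dye fit. Array numbers in the labels are not stated to be batches and were not used.

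Genes were named by a rule fixed before the data were examined: up to 10 clones with the largest mean dye component among calls, up to 15 from the between-pool F-test among calls, 10 with the smallest p in the even-odd test, and up to 3 members of each list with the smallest F-test p, leaving out clones without a single symbol. Other genes are said to be chosen after their values were seen.

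The tests were run on simulated data with the technical spread of the real clones, from the between-pool fit, and 200 changed clones. Of changes of 0.5, 1 and 1.5 log2 units, the dye test recovered 94.0%, 98.5% and 100%, the even-odd test 95.5%, 100% and 100%, and the between-pool F-test, for a change in 1 pair, 0%, 47.8% and 93.9%. Clones called without a change numbered 11, 11 and 18 of 8448 run. The simulation held no pool differences other than those added. Such differences enter the error of the real even-odd test, so its recovery on the real data may be lower. Alternatives tried were no centring, scaling of the spread, quantile normalization, single spots, the other reading of the direction, each pair left out, robust eBayes, a 1% threshold, fits with and without a replicate block, no dye term, and settings added later. A relaxed filter on missing values moved nothing, as none was missing. Array files carry no sequencing depth, and the number of arrays limits the precision.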

Results

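The series measured how far log ratios stray when both samples on an array were treated alike. On a 2-colour *Drosophila* cDNA array, 8 pools of ethanol-treated female flies were compared in 4 pairs, each pair on a normal-label and a reversed-label array, so that each label group holds 4 arrays. Pools were separate pools of flies, and the 2 arrays of a pair carried the same RNA. No treatment contrast exists among these samples. The number of arrays limits the precision of every value, and the log base was inferred.

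The first question was how many clones appear changed between identically treated pools. On single arrays, 2.02% ± 2.33 (SD, n = 8 arrays) of the 8448 clones lay past 2-fold. The normal-label array of pair 3 stood at 7.63% (645 clones), and the others ranged from 0.604% (normal label, pair 4) to 1.88% (reversed label, pair 2). Without that array of pair 3 the share was 1.22% ± 0.561 (SD, n = 7 arrays), and without pair 3 it was 1.30%. After the dye swap was averaged out, the share was 0.852% ± 0.574 (SD, n = 4 pairs), with 0.545%, 0.959%, 1.61% and 0.296% in pairs 1 to 4. At least 1 array of 8 put 1083 clones (12.8%) past 2-fold, at least 1 averaged pair 264 (3.13%), and no clone was past 2-fold in all 4 averaged pairs. Pair 3 weighs on both counts, with 645 clones on its normal-label array and 136 in its average. Averages in dye orientation, which keep the dye, put 0.556%, 0.817%, 0.734% and 0.402% of clones past 2-fold in pairs 1 to 4. The lower share after averaging thus cannot be credited to cancelling the dye. Duplicate spots of a clone correlated at 0.251 to 0.569, against 0.038 to 0.122 for neighbouring spots of different clones.

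**Figure D1:**
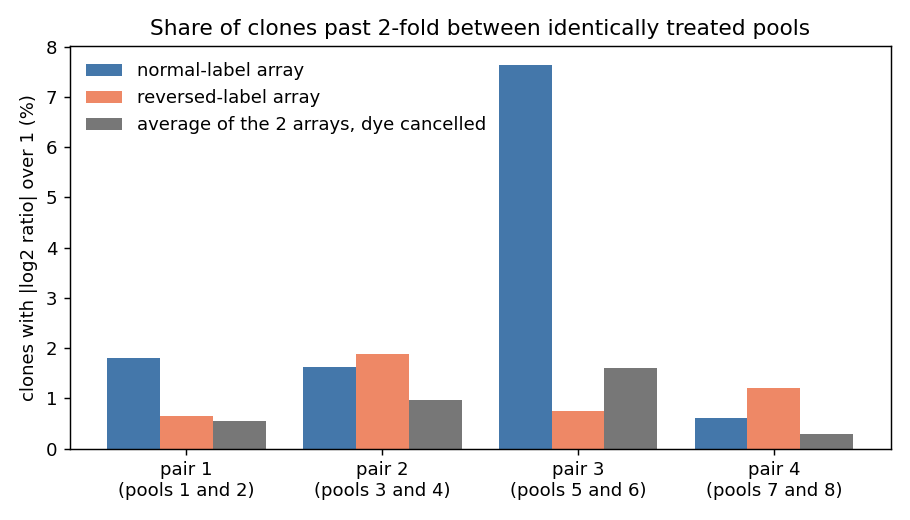
Bars give the percentage of 8448 clones with an absolute log2 ratio over 1, per pair of pools, on the normal-label array, on the reversed-label array and after averaging the 2 arrays so that the dye cancels. The normal-label array of pair 3, at 7.63%, stands above the other arrays, which lie at 1.88% or lower.

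Array profiles followed the label group. With signs as deposited, the 4 normal-label arrays correlated with each other at 0.186 to 0.435 across clones, and with the reversed-label arrays of other pairs at -0.412 to 0.128 (median -0.157, 9 of 12 below 0). The reversed-label arrays of pairs 1, 2 and 4 correlated with each other at 0.125 to 0.356. The reversed-label array of pair 3 stood apart, at -0.142 to 0.032 with the other reversed-label arrays and -0.003 to 0.222 with the normal-label arrays. Clones are not independent replicates, and no p-value is attached to these coefficients.

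**Figure D2:**
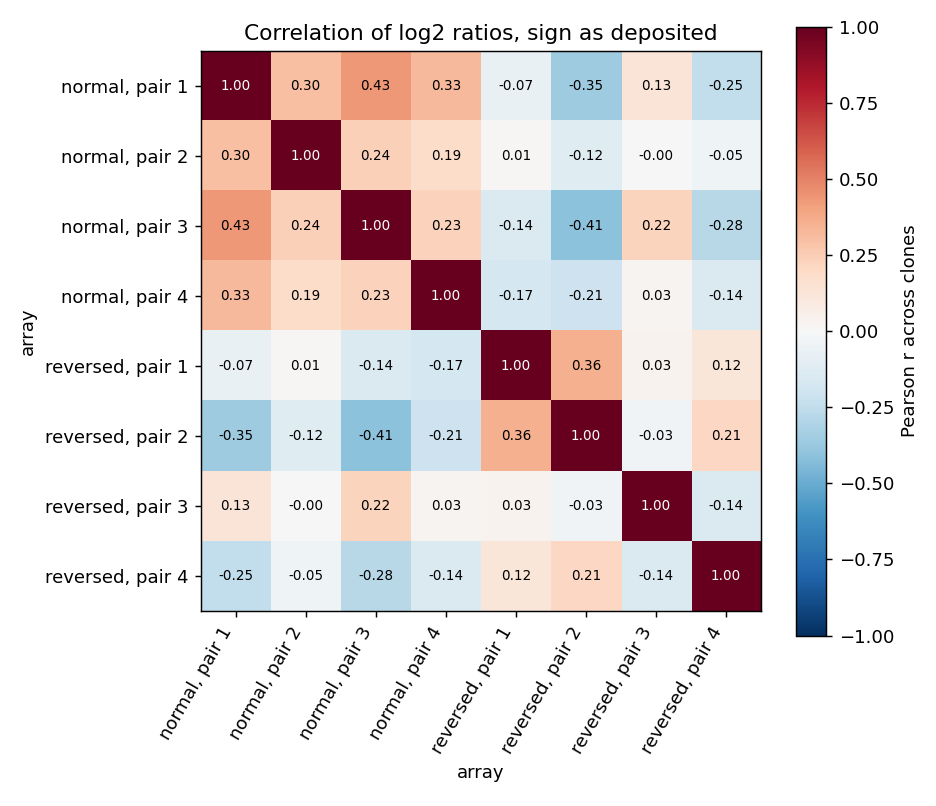
Pearson correlations across 8448 clones between the 8 arrays, with the sign of the ratios as deposited and colour from -1 to 1. Normal-label arrays correlate with each other at 0.186 to 0.435, and the reversed-label array of pair 3 lies between -0.142 and 0.222 with every other array.

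The dye component, the part of the ratio that stays with the dye when pools are exchanged, gave the most calls. The rule that set the orientation assigns to it what the pairs share. Under the other reading of the direction its calls went to the even-odd component. In the limma test over 4 pairs, 723 of 8448 clones passed 5%, 359 higher in dye A and 364 higher in dye B, and 237 of them carried a gene symbol (95 and 142). Only 15 of the calls exceeded 2-fold. Among calls with a gene symbol, the largest excess in dye A was held by the clone of *alphaTub85E*, an alpha-tubulin (1.82 ± 1.05, mean log2 ratio ± SD, n = 4 pairs, adjusted p = 0.0259). Next came *Hsc70-2*, a constitutive member of the Hsp70 chaperone family, whose 2 clones gave 1.63 ± 0.72 and 1.59 ± 0.41 (adjusted p = 0.0186 and 0.01). *Hsc70-1*, of the same family, gave 1.18 ± 0.10 (adjusted p = 0.00251) in the clone named by the rule, a second clone gave 0.90 ± 0.53 (adjusted p = 0.0288) and the other 0.14 ± 0.12 (adjusted p = 0.261), so clones of this gene differed. The SD of 0.10 is over pair means, in which opposite deviations of the 2 arrays cancel. In pair 3 the clone named by the rule stood at 2.99 (normal label) and 0.62 (reversed label), signs as deposited. A dye effect alone would give opposite signs there. The *Hsc70-2* clones were also above 0 on that reversed-label array (0.13 and 0.63). With robust eBayes the *alphaTub85E* clone did not pass (adjusted p = 0.0834). Members of the Hsp70 family share sequence, and a spotted cDNA may bind transcripts of several of them.

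*CG18858* (1.22 ± 0.50), the ribosomal protein gene *RpS10a* (1.12 ± 0.61), the tropomyosin gene *Tm2* (1.10 ± 0.43), *CG16782* (0.94 ± 0.21) and *CG9747* (0.90 ± 0.35) were also higher in dye A, with limma adjusted p between 0.0101 and 0.0241. *Wnk*, which encodes a protein kinase, was furthest towards dye B among calls with a gene symbol, at -1.02 ± 0.11 (limma adjusted p = 0.00346). A clone of *Obp56d* that was not called lay further, at -1.52 ± 2.97 (limma adjusted p = 0.352). For each of these clones the even-odd mean had the sign of the dye mean. Averaged over pairs, ratios were thus larger on normal-label than on reversed-label arrays. Examples were 0.88 for each *Hsc70-2* clone and -0.32 for *Wnk*, none of which passed the even-odd test (limma adjusted p = 0.821). Pairs differed, with the *Hsc70-2* clones at 2.26 and 2.53 in pair 3 but -0.26 and -0.18 in pair 2. Of the dye clones named by the rule, only *RpS10a* (0.19) and *CG9747* (0.016) kept the sign in pair 2. The count of dye calls was 314 with arrays scaled to one spread, 404 with quantile normalization, 95 with single spots as rows, 3 at a 1% threshold, 481 with the reversed-label array of pair 3 turned in sign, 0 with either label group alone and 0 under the other reading of the direction. It also rested on the set of pairs, at 3, 4, 21 and 359 without pairs 1, 2, 3 and 4, and fell to 0 when the 8 arrays were taken as independent, without the pair as a block. With 1 array left out and the remaining 7 taken as independent, it was 501 without the reversed-label array of pair 3 and 0 without any of the other 7.

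**Figure D3:**
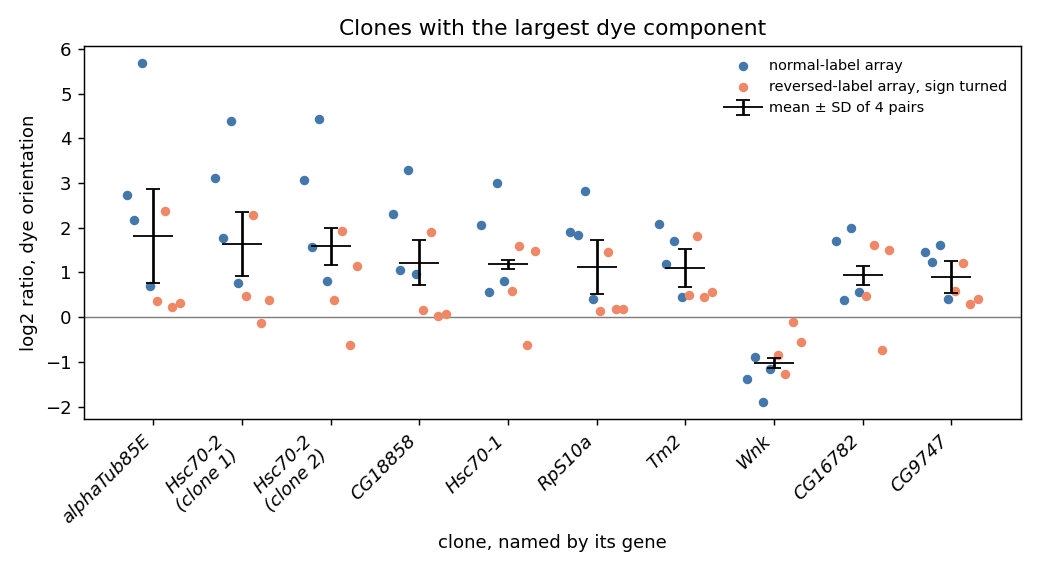
Log2 ratios in dye orientation (y axis) of the 10 clones with the largest absolute mean dye component among calls with a gene symbol (x axis). A point is given per array, with the mean ± SD of 4 pairs. *Wnk*, at -1.02, is the clone of the 10 that lies below 0, and points of normal-label arrays reach further from 0 than those of reversed-label arrays for most clones.

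Grouped by the fixed lists, heat shock and chaperone clones, 15 of 5 genes, leaned to dye A. Of the 15, 6 passed, all towards dye A, among them *Hsp68* (0.81 ± 0.23) and 1 of 8 *DnaJ-1* clones (0.32 ± 0.10). The other 9 did not pass, with 6 calls adjusted over the list alone. In camera, chosen for this component after the data were seen, the list was shifted towards dye A (adjusted p = 0.00093), and adjusted p = 0.523 with an estimated correlation. Nervous system clones leaned to dye B (adjusted p = 0.00623, and 0.523 with an estimated correlation): of 6 clones, the potassium channel genes *Sh* (-0.37 ± 0.07) and *slo* (-0.41 ± 0.16 in 1 of 2 clones) passed, and 5 passed adjusted over the list alone. The reversed-label array of pair 3, which stood apart from the other reversed-label arrays, enters all of these values.

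Other lists had no shift past 5%. Mitochondrial oxidative phosphorylation had 3 of 9 clones past the threshold, *ND-B8* (-0.60 ± 0.21) and *ND-13A* (-0.45 ± 0.07, in 1 of 2 clones) towards dye B and *ND-51* (0.36 ± 0.04) towards dye A, and 5 adjusted over the list alone. Muscle had 3 of 6, *Tm2* towards dye A and the troponin C genes *TpnC41C* (-0.69 ± 0.20) and *TpnC73F* (-0.35 ± 0.16) towards dye B, the same 3 adjusted over the list alone. Both superoxide dismutase clones of the antioxidant list, *Sod3* (0.78 ± 0.36) and *Sod2* (0.75 ± 0.47), passed towards dye A, while 2 of 4 clones did not pass, and 2 passed adjusted over the list alone. Odorant-binding proteins had 3 of 27 past the threshold (*Obp57c* -0.55 ± 0.06, *Obp56e* -0.30 ± 0.11, *Obp99c* 0.60 ± 0.40) and 4 adjusted over the list alone. Ribosomal proteins had 2 of 14 (*RpS10a* above and *RpS28b* at -0.38 ± 0.05), and 2 adjusted over the list alone. Of these 14 clones, 9 were of *RpL32*. Single clones passed in the cytochrome P450 list (*Cyp6u1*, 0.37 ± 0.17, of 3), the UDP-glycosyltransferases (*Ugt35D1*, -0.38 ± 0.11, of 7) and the ovary germline list (*mael*, -0.41 ± 0.05, of 3), each also 1 adjusted over the list alone. None passed over all clones among yolk and fat body (3 clones), glutathione S-transferases (3), circadian clock (6), male reproductive tract (7), eye (5), cuticle (4), and the single clones for immunity (*Dif*), gut enzymes (*mag*) and alcohol metabolism (*Aldh-III*). Adjusted over the list alone, 1 cuticle clone passed. *Cyp6u1* and *TpnC73F* did not pass with arrays scaled to one spread (adjusted p = 0.0808 and 0.112) or with quantile normalization (0.0771 and 0.119), *ND-13A* did not with scaled arrays (0.0512), and *TpnC73F* and *ND-13A* did not with the pair as a replicate block (0.191 and 0.0525). The eggshell list had 0 clones with a symbol. The mean and median of a list differed in sign for muscle (0.0025 and -0.11), ribosomal proteins (0.02 and -0.025) and the ovary germline list (-0.07 and 0.05). *Obp56e*, *Obp99c*, *slo*, *ND-51* and the *DnaJ-1* clone were chosen after their values were seen.

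The even-odd component is a null comparison, since parity carries no treatment. In the limma test 0 of 8448 clones passed 5% (smallest adjusted p = 0.821), and 451 (5.34%) had an unadjusted p under 0.05. The smallest p-values among named clones belonged to *Tif-IA*, an RNA polymerase I initiation factor gene (0.44), *Glut4EF* (-0.41), *Vps2* (-0.47), *Pop2* (0.59), *Rpt4R* (0.48), *CG7886* (-0.46), *CG33284* (-0.45), *fabp*, a fatty acid binding protein gene (0.38), *Cyp1* (0.77) and *Obp19c* (-0.34), each a mean log2 value of 4 pairs with the same sign in 4 of 4 pairs. None of them passed. Adjusted over the list alone, 1 fixed list member passed, *betaTub85D* of the male list (0.31), chosen after its value was seen. Second clones of *Glut4EF* (0.07), *Vps2* (-0.17), *CG7886* (0.14) and *Obp19c* (-0.13) lay closer to 0. The same fit taken over 8 arrays without or with the pair as a replicate block also gave 0 calls, and under the other reading of the direction the component took the 723 calls.

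Differences between the pools of single pairs were tested against the technical spread of the dye-swapped arrays. In the limma F-test over the 4 pairs, 0 of 8448 clones passed 5%, the smallest adjusted p being 0.0843 for *Hsc70-1*, and 1262 clones (14.9%) had an unadjusted p under 0.05. There were 3 calls without pair 4 and 8 without the reversed-label array of pair 3. Pairs 1, 2 and 4 gave 0 calls each, with 549, 625 and 453 clones at an unadjusted p under 0.05. Pair 3 (pools 5 and 6) gave 270 calls, 133 higher in the numerator pool and 137 lower. Among clones named by the rule these included 1 of 2 clones of *Hsc70-2* (2.53, adjusted p = 0.0233, the other at 2.26 with adjusted p = 0.0527), 1 of 3 clones of *Hsc70-1* (1.81, adjusted p = 0.00951) and *CG16782* (1.37) on the higher side and the muscle gene *TpnC41C* (-1.39, adjusted p = 0.0233) on the lower side. The pair 3 calls overlapped the dye component, with 168 of 270 past 5% in both tests. They ended (0 calls) with arrays scaled to one spread, with quantile normalization, with single spots as rows, under the other reading of the direction, with slopes on the dye component removed, and when the reversed-label array of pair 3 was turned in sign, and numbered 3 at a 1% threshold, 2, 3 and 157 without pairs 1, 2 and 4 and 87 without the reversed-label array of pair 3.

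Gene lists passed in 5 of 76 camera tests of the pair coefficients at an inter-gene correlation of 0.01, and in 0 with an estimated correlation (adjusted p = 0.758 for each of the 5). In pair 1, the heat shock and chaperone list was higher in the numerator pool (median 0.26, 15 clones of 5 genes, camera adjusted p = 3.22e-05). The odorant-binding list was lower (median -0.15, 27 clones of 21 genes, camera adjusted p = 0.0486). Clones of the same gene entered as separate members. None of the clones of either list passed in that pair, the *Hsc70-2* clones standing at 1.34 and 1.32 (adjusted p = 0.45 and 0.679) and the *Hsc70-1* clones at 0.73, 0.66 and 0.10 (adjusted p = 0.418, 0.815 and 0.963). In pair 3, the oxidative phosphorylation list was lower (median -0.53, adjusted p = 0.0171), with 2 of 9 clones passing, *ND-B8* at -1.14 and 1 clone of *ND-13A* at -0.99. The nervous system list was lower (median -0.42, adjusted p = 0.0312), but 0 of 6 clones passed, *nSyb*, a synaptic vesicle protein gene, standing at -0.57 (adjusted p = 0.0606). The heat shock and chaperone list was higher (median 0.27, adjusted p = 0.0486), with 2 of 15 clones passing, the *Hsc70-2* and *Hsc70-1* clones above. The number of lists was 2 with slopes removed and 3, 3 and 1 without pairs 1, 2 and 3. The medians of these lists in the dye component had the same sign (0.18 for heat shock, -0.10 for odorant-binding proteins and for oxidative phosphorylation, -0.25 for the nervous system). In pair 1, slopes on the dye component of the other pairs were unequal in size, at 0.99 (normal label) and -0.34 (reversed label), signs as deposited. The list shifts of pair 1 may thus hold an unequal dye effect, which cannot be parted here from a pool difference along that component. No list passed in pairs 2 and 4. In the F-test, calls adjusted over the list alone numbered 4 for heat shock, 3 for odorant-binding proteins (*Obp56g*, *Obp57c* and *Obp99a* had the smallest p), 2 each for muscle, oxidative phosphorylation and ovary germline (*exu* and *mael*), and 1 each for the eye (*Galphaq*), cuticle (*Lcp65Ag3*) and male (*ocn*) lists, against 0 over all clones.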

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

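The tests of explanations for pair 3 and the settings that turn or correct its arrays were chosen after the result was seen; the splits of the arrays were planned before their counts were seen. Of 34 groups of 4 values examined, 1 held a value far from the rest, and chance gives about 1 in 20. The robust SD of the pool difference was 0.32 in pair 3, against 0.18 in each of the other pairs.

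The 270 clones called between pools 5 and 6 were weighed first. A pool difference unrelated to dye would take the sign of the dye component of the other pairs in about 50% of calls, and 93.7% did (253 of 270), against 64.0% of all clones in pair 3 and 34.8% to 61.1% (SD 13.2, n = 3 pairs) of the 270 clones with the smallest p in each other pair, which argues against it as the whole source but leaves it open for part of the calls. An unequal dye effect on the 2 arrays of the pair would also give such calls. With signs as deposited, the slopes on the dye component of the other pairs were 1.51 (normal label) and 0.15 (reversed label). With each array's slope removed, 0 of the calls were left. The removal takes away any difference that runs along the dye component, whatever its source. It therefore cannot part an unequal dye effect from a pool difference along that component. The median absolute coefficient of the 270 called clones fell from 0.86 ± 0.33 (SD) to 0.61 ± 0.31 on removal. Its standard error rose from 0.14 to 0.17, so part of the difference stays open. Whether the reversed-label array was hybridized in the normal orientation cannot be told from its slope. The slope shows which dye is the numerator of the value, not which pool carried that dye. At 0.15 it lies between those of the other reversed-label arrays (-0.94 to -0.34) and of the normal-label arrays (0.47 to 1.51). Whether the numerator dye was that of the normal-label arrays thus cannot be told either. The slope has the sign of the normal-label arrays. A weak dye effect with the numerator dye of the other reversed-label arrays would not give this sign alone.

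For the 723 dye calls, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many, and the highest other split gave 6. The arrays are paired by shared RNA, however, and 27 of these splits put both arrays of some pair on one side, so that pool differences enter. Only 8 part every pair as the real one does; the other 7 of them gave 0 calls, and 8 splits are too few for a share under 0.05, so the share of all 35 planned beforehand is not used. For the even-odd component, with 0 calls, 35 of 35 splits gave as many and the highest other gave 0, an outcome that a count of 0 fixes in advance, so nothing follows from it.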

How the results depend on the processing

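Settings that turn or leave out an array of pair 3, remove slopes, or use 1 label group alone were chosen after the data were seen. The even-odd component, with 0 calls, changed only under the other reading of the direction, where it took the 723 calls and the dye component fell to 0, pair 3 to 0, and *mael* turned from -0.41 to 0.033. The dye count was 314 with scaled arrays, 404 with quantile normalization (399 shared with the 723), 95 with single spots, 3 at a 1% threshold (*Hsc70-1*, *Wnk* and an unnamed clone), 481 with the reversed-label array of pair 3 turned, and 0 with normal-label or with reversed-label arrays alone. With pairs left out in turn it ranged from 3 to 359. It was 0 without the replicate block, a fit whose residual also holds the pool differences that cancel within a pair, and 826 with the pair as a replicate block, which left the even-odd count at 0 and ended the calls of *TpnC73F* and *ND-13A* among 23 clones named by the rule; it was not run for the between-pool test, which already holds a term per pair. Of these 23 clones, 20 stayed past the threshold with scaled arrays, 21 with quantile normalization, 22 with robust eBayes, 2, 2, 5 and 20 without pairs 1 to 4, 2 at a 1% threshold, and 0 without the block. The 10 clones named from the even-odd test stayed short of it except *Rpt4R* under the other reading of the direction.

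Pair 3 gave 0 calls with scaling, quantile normalization, single spots, slopes removed or its reversed-label array turned, 3 at 1%, 87 with that array left out, and 2 to 157 with pairs left out. Pair 1 gave 1 call (*Scsalpha1*, chosen after its value was seen) with quantile normalization. The between-pool test gave 8 calls with that array left out and 0 to 3 with pairs left out, the 3 calls, without pair 4, being both *Hsc70-2* clones and an unnamed clone. Gene lists per pair fell from 5 to 0 with an estimated correlation, 2 with slopes removed, and 3, 3, 1 and 4 without pairs 1 to 4. Lists on the dye component fell from 2 to 0. Where no value above shows it, the cause was not tested. Shares past 2-fold stayed within 1 SD, which the normal-label array of pair 3 widens: without it the share on single arrays was 1.22% ± 0.561 (SD, n = 7 arrays), and without pair 3 it was 1.30%. The means and medians of lists that passed kept their sign under every scaling. The list tests themselves were not rerun with scaled or quantile-normalized arrays. Signal over background was not analysed here.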

Other observations

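The tests in this part were chosen after the result was seen. A set of 70 clones lay under -0.6 (log2, averaged over the dye swap) in both pair 1 and pair 2, where 2.83 would be expected from 136 and 176 such clones in each, and 0 lay above 0.6 in both. The threshold was chosen after the values were seen. The mean was -0.86 ± 0.22 in pair 1 and -1.08 ± 0.40 in pair 2 (SD, n = 70 clones), but 0.04 ± 0.23 in pair 3 and -0.07 ± 0.11 in pair 4, and 0 of the 70 were dye calls. On all 4 arrays of pairs 1 and 2, 53 clones lay under -0.5 and 0 above 0.5. Named members, chosen after their values were seen, include the fumarase gene *Fum4*, the translation initiation factor gene *eIF4E5*, *tomboy20*, *TTLL6B* and *CG15461*. No clone of the set passed the F-test over all clones (smallest limma adjusted p = 0.121). In successive runs of 528 spots, 60 of the 70 fell at positions 409 to 480, where 9.55 would be expected; the spot layout is not given in the sources used here.

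A pool difference in the annotated genes would move their other clones as well, but for the 24 members whose gene had further clones these, members of the set included, had a median of -0.048 (SD 0.20). Of the 24, however, 9 share their gene with another member: *CG12902* (3 of its 14 clones), *CG8517* (2 of 8), *CG33704* (2 of 4) and *CG30430* (2 of 5), chosen after their values were seen. Over all clones of the gene, set members included, the median was -0.0025 (SD 0.45) in *CG12902*, above -0.6 by more than its SD, and -0.12 (SD 0.50) in *CG8517*, -0.51 (SD 0.61) in *CG33704* and -0.61 (SD 0.26) in *CG30430*. Over the clones outside the set the medians were 0.05, -0.09, 0.02 and -0.55 in the same order, and since members were picked for low values and the rest for lacking them, a pool difference stays open for the last 3 genes. *CG30430* is the gene of the 4 whose clones outside the set were also low, and 1 of the *CG8517* members was low on the normal-label arrays of pairs 1 and 2 (-3.08 and -2.35) but not on the reversed-label arrays (0.06 and 0.38). The 46 members without a further clone of a named gene were not tested. An even shift of the spot positions would move the other clones there, which had a median of -0.0093 (SD 0.21). RNA of whole males in a pool of each pair would move the 7 clones of the fixed male list, whose median was -0.11 (SD 0.25); that list was written before the data were examined and holds none of the 70. The medians over the 24 members, the positions and the male list each lie above -0.6 by more than their SD. That bound is the cut that picked the set, however. The 7 male clones, of 6 genes, were not picked for low values and need not reach it. The male list therefore leaves RNA of males open. Inserts that differ from the annotation, or a transcript shared by these wells, may account for the set, and neither was tested because clone sequences were not used here.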
